A study of Komagataella phaffii with 18 samples.

How the data were processed

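Polyadenylated RNA of Komagataella phaffii strain CBS2612, a methylotrophic yeast, was sequenced in 18 libraries. The labels place them in 6 groups of 3, formed by 3 strains (wild type, heterothallic a-type and heterothallic α-type) in YPD, a rich medium, during exponential growth, and after the same cultures had spent 24 h in acetate medium. Whether the 3 samples of a group came from separate cultures is not stated, so p-values measure the spread between these samples, which may be technical.

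Each sample had a kallisto table that the authors deposited, with estimated counts and TPM for 5341 features, per the file headers. Estimated counts are read numbers that need not be whole, because kallisto divides a read that matches several transcripts among them. The submitters' processing notes name TopHat2, FastQC 0.11.2, Trim Galore 0.4.2, kallisto, SAMtools and DESeq2 without role or order, and the genome build is not given in the sources used here. The deposited TPM values were read but entered no test. The 9 tables of the whole series hold the authors' normalized counts, a signal scaled between libraries, per their file names. Of these, 2 write decimals with commas and were not used. The other 7 served only as a check against the deposited estimated counts. The ratio of the deposited normalized value to the estimated count varied between features, with a range from the 5th to the 95th percentile of 0.377% to 9.72% of its median, so the normalized values were not used in a test. The tables named for α-type against a-type and α-type against wild type in acetate held the same bytes as the table for wild type in acetate against YPD, so these 3 tables are identical files.

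The feature IDs carry no gene names in the files. The reference gene table given with the data is for assembly ASM2700v1 of another strain, GS115, and 0 of the 5341 IDs matched it. The 18 gene lists fixed beforehand had 0 members that could be identified by ID. The gene list tests, the cell type markers and the check of the mating-type locus were therefore not run, and features are reported by ID. A match by length and order was not used to identify features. Lengths were whole multiples of 3 for 99.9% of features and are called coding lengths.

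Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Features with enough counts for their group (filterByExpr) were kept, which left 4783. Libraries were scaled by TMM, the 18 libraries were fitted together with 1 mean per group, and quasi-likelihood tests gave p-values adjusted by the Benjamini-Hochberg method over the 4783 features, with a threshold of 0.05. There were 12 comparisons: acetate against YPD in each strain, the 3 strain pairs in each medium, and the 3 differences between strains in the response to the medium (interactions). CPM values are counts scaled by the TMM-adjusted library sizes. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. Floors and the counting interval of a ratio cover counting error only, and the other 95% intervals come from the fitted spread between replicates.

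Features named in the text follow a rule written before the data were examined: among features past the threshold with at least 10 CPM in the higher group and replicates that do not overlap, the largest changes, limited to 2 rising and 2 falling IDs per comparison because the IDs have no names. For interactions, the acetate replicates of the strains must not overlap. Any other ID is said to be chosen after its values were seen. Chance alone separates 3 libraries from 3 in 10% of features.

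The deposited depth was low. Total estimated counts ran from 234044 to 309362 in the 9 YPD libraries and from 637339 to 765524 in the 9 acetate libraries, so the mean acetate total was 2.44 times the mean YPD total. A count of 0 in a YPD library with a total of 297754 allows up to 10.3 CPM. Pairs of replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 2.15 to 16.2, so none was counted as a repeat of another.

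The tests were checked on simulated counts with the real means, spreads and depths and 200 changed features. For wild type in acetate against YPD, 24% of 2-fold and 86% of 4-fold changes passed, and 9.84% of the calls were false. For a-type against α-type, 31% and 81% passed in YPD with 28.7% of the calls false, and 28% and 95% passed in acetate with 0 false calls. For a-type against wild type in acetate the shares were 29% and 93%, with 0 false calls. For the interaction of a-type with α-type, simulated with 4-fold changes only, 61.5% passed in the joint fit with 5.38% of the calls false, and 59.5% passed with the own spread of each medium with 3.25% false. For wild type above both strains in acetate, 98% of 4-fold changes passed with 0 false calls when wild type otherwise equaled the higher strain. The spread shared by all 18 libraries is thus too small for YPD and too large for acetate.

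The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, a filter of 10 CPM in 3 libraries, no filter, effective-length offsets, a test against a log2 fold change of 1 (glmTreat), fits of the compared libraries alone, a replicate block and leaving out each library. A fit of the 9 libraries of a medium, acetate libraries thinned to the mean YPD total of 283184, summed counts of mirrored feature pairs, and interactions with each medium fitted alone, where the difference of the log2 fold changes was set against the combined standard error, were added after the data had been seen. These interactions were first computed without adjustment, and with other degrees of freedom, for the 19 features that differed between a-type and α-type in acetate, before they were run over all tested features. Figures were drawn with matplotlib 3.10.9.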

Results

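The study compared gene expression of wild-type K. phaffii with that of heterothallic a-type and α-type cells in YPD and after 24 h in acetate medium, which was used to induce mating genes. Wild-type K. phaffii can switch its mating type, whereas a heterothallic strain keeps a single one. Each of the 6 groups had 3 libraries. Between 4976 and 5168 features had counts in a YPD library, and between 5230 and 5284 in an acetate library. The medium separated the libraries along the main principal component, which held 58.7% of the variance, and the next component, with 9.45%, separated wild type from both heterothallic strains in acetate. Replicates spread more in YPD, where the biological coefficient of variation was 34.5% in wild type, 39.3% in a-type and 31.6% in α-type, than in acetate, where it was 12.9%, 13.3% and 11.2%.

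**Figure D1:**
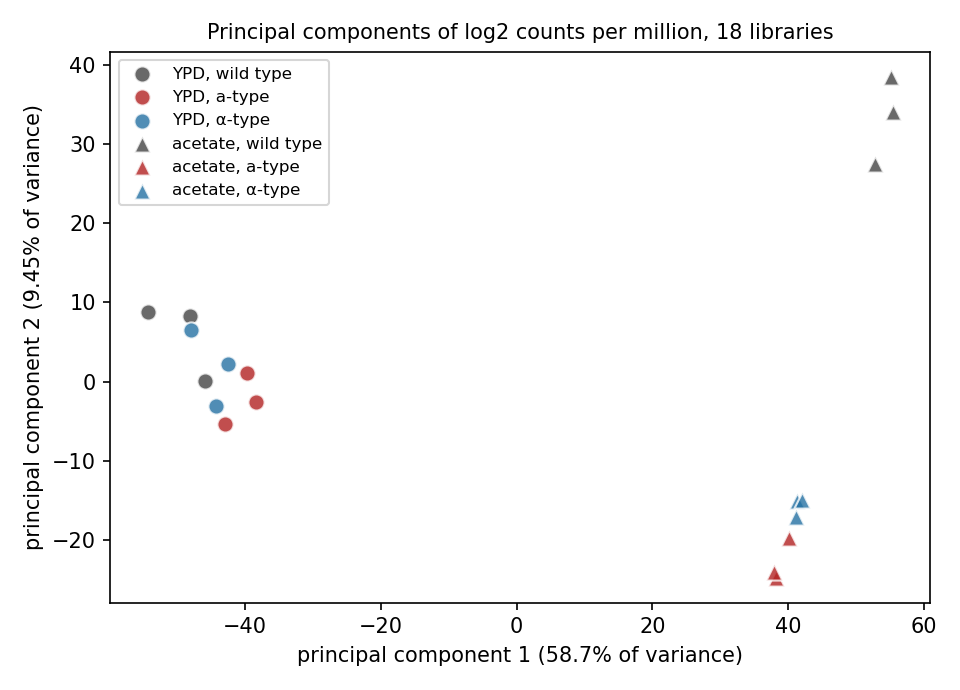
Each point is a library, placed by principal components 1 and 2 of log2 CPM, with color for the strain and shape for the medium. The 9 YPD libraries lie at negative values of component 1, the 9 acetate libraries at positive values, and the 3 wild-type acetate libraries lie above all others on component 2.

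A large share of the transcriptome differed between YPD and acetate in all 3 strains. The YPD samples were in exponential growth and the acetate samples came from the same cultures 24 h later. An effect of the medium therefore cannot be told apart from one of time or growth phase. In wild type 1224 features rose and 1115 fell, in a-type 972 rose and 918 fell, and in α-type 1066 rose and 938 fell. Which direction held more features depended on the processing. In wild type 1067 rose and 1321 fell with upper-quartile scaling. With the compared libraries fitted alone, 1060 rose and 1094 fell in wild type, 801 and 835 in a-type, and 1025 and 1040 in α-type. PP7435_Chr1-0175 rose from 63.4 ± 11.6 to 12342 ± 935 CPM in α-type (SD, n = 3; log2 fold change 7.60, SE 0.28, adjusted p = 2.85e-16), and its acetate means were 12699 ± 1260 CPM in wild type and 11561 ± 1245 CPM in a-type. PP7435_Chr3-0228 fell in every strain, with log2 fold changes of -7.61 in wild type (from 2670 ± 2465 to 12.9 ± 9.41 CPM, SE 0.70, adjusted p = 3.24e-09; -6.54 without YPD wild-type replicate 3, which had 5506 CPM), -5.25 in a-type (from 536 ± 342 to 13.8 ± 5.20 CPM, SE 0.65, adjusted p = 7.5e-07) and -6.51 in α-type (from 975 ± 332 to 10.5 ± 3.34 CPM, SE 0.68, adjusted p = 4.37e-08). PP7435_Chr4-0656 fell from 2404 ± 1199 to 19.1 ± 2.39 CPM in a-type and from 2619 ± 852 to 18.8 ± 9.16 CPM in α-type.

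Other features also rose strongly. PP7435_Chr2-0522 went from 26.03 ± 10.03 to 13279 ± 2274 CPM in wild type (log2 fold change 9.02, SE 0.30, adjusted p = 9.41e-17) and from 15.8 ± 0.71 to 12522 ± 835 CPM in α-type (log2 fold change 9.60, SE 0.31, adjusted p = 5.23e-17). PP7435_Chr1-1164 had 0 counts in YPD wild type and 483 ± 77.8 CPM in acetate wild type, at least 127-fold higher. In a-type, PP7435_Chr4-0893 had 0 counts in YPD and 815 ± 130 CPM in acetate, at least 262-fold higher, and it went from 1.14 ± 1.98 to 199.9 ± 28.9 CPM in wild type and from 1.10 ± 1.91 to 16.8 ± 9.98 CPM in α-type. PP7435_Chr1-2225 had 0 counts in YPD and 90.5 ± 18.98 CPM in acetate in a-type, at least 29.0-fold higher, and it went from 11.1 ± 5.38 to 160 ± 46.4 CPM in wild type and from 4.47 ± 1.61 to 93.8 ± 9.32 CPM in α-type.

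The responses of the strains shared many features. In all 3 strains 664 features rose and 589 fell, where independent lists of these sizes would share 55.4 and 41.97, and these comparisons share no libraries. Of the 3017 features past the threshold in any strain, 28 rose in one strain and fell in another. Across features, which are not independent replicates, the log2 fold changes correlated at 0.764 between wild type and a-type, 0.799 between wild type and α-type and 0.883 between a-type and α-type. Rising features made up 27.5% of those tested on chromosome 1 in wild type and 24.6% on chromosome 2, the extremes among the 4 chromosomes. Of the 3 mitochondrial features tested, 1 passed the threshold, PP7435_Mit-0025, chosen after its values were seen, which fell by 1.38 in wild type (adjusted p = 0.0061). Tested against a log2 fold change of 1, 1151 features passed in wild type, 685 in a-type and 805 in α-type.

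The comparison of a-type with α-type addresses what differs between the mating types. Each type was represented by a single heterothallic strain, so any other difference between these strains cannot be told apart from mating type. In YPD, 3 features passed the threshold and all lie on chromosome 4. PP7435_Chr4-1037 had 287 ± 95.9 CPM in a-type and 1.26 ± 2.19 CPM in α-type, where 1 count was seen, a ratio of 250 by counts and library sizes summed over each group, with a 95% counting interval of 44.5 to 9919 (adjusted p = 4.46e-07). PP7435_Chr4-1169 was higher in a-type, at 476 ± 240 against 55.3 ± 17.8 CPM (log2 fold change 3.11, SE 0.33, adjusted p = 5.03e-06). PP7435_Chr4-0073 was lower in a-type, at 22.0 ± 16.7 against 192 ± 42.2 CPM (log2 fold change -3.08, SE 0.43, adjusted p = 0.000368), but it lost the threshold when the 6 compared libraries were fitted alone (log2 fold change -3.04, adjusted p = 0.153) and when the 9 YPD libraries were (log2 fold change -3.06, adjusted p = 0.0581). In acetate, PP7435_Chr4-1037 had 0 counts in α-type, PP7435_Chr4-1169 had a log2 fold change of 1.21 (SE 0.29, adjusted p = 0.0836), which did not pass, and PP7435_Chr4-0073 one of -2.13 (SE 0.35, adjusted p = 0.00132). An unadjusted p under 0.05 was found for 241 features in YPD and 94 in acetate, where about 239 would have one with no change and a correct spread. The joint spread behind these p-values is too small for YPD and too large for acetate. Neither count can therefore be read as more or fewer than chance.

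In acetate, 5 features were higher in a-type and 14 in α-type. PP7435_Chr2-0522 had 45.0 ± 7.14 CPM in a-type and 12522 ± 835 CPM in α-type (log2 fold change -8.11, SE 0.27, adjusted p = 1.13e-16). PP7435_Chr4-1158 had 0 counts in all 6 a-type libraries of both media, which allows up to 0.982 CPM over these libraries, and 392 ± 21.8 CPM in acetate α-type, at least 274-fold higher. In the other direction, PP7435_Chr4-1037 had 148 ± 20.1 CPM in a-type and 0 counts in α-type, at least 110-fold higher in a-type, and PP7435_Chr4-0893 had 815 ± 130 against 16.8 ± 9.98 CPM (log2 fold change 5.56, SE 0.39, adjusted p = 1.68e-09). The wild-type mean lay between the heterothallic means for all 5 features higher in a-type. Of the 14 higher in α-type, the wild-type mean lay above both strains for 13 and differed from α-type past the threshold for 9. Of these 14, PP7435_Chr4-0003, chosen after its values were seen, is uncertain because kallisto can divide its reads with PP7435_Chr4-0072: with mirrored copies summed, 18 features passed, 5 higher in a-type and 13 in α-type, and the summed pair was higher in a-type by 0.92 (adjusted p = 0.0999), which did not pass. The count of 19 became 55 when the 6 libraries were fitted alone and 11 when tested against a log2 fold change of 1, and it was 11 without α-type replicate 2 or without any of the a-type acetate replicates.

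**Figure D2:**
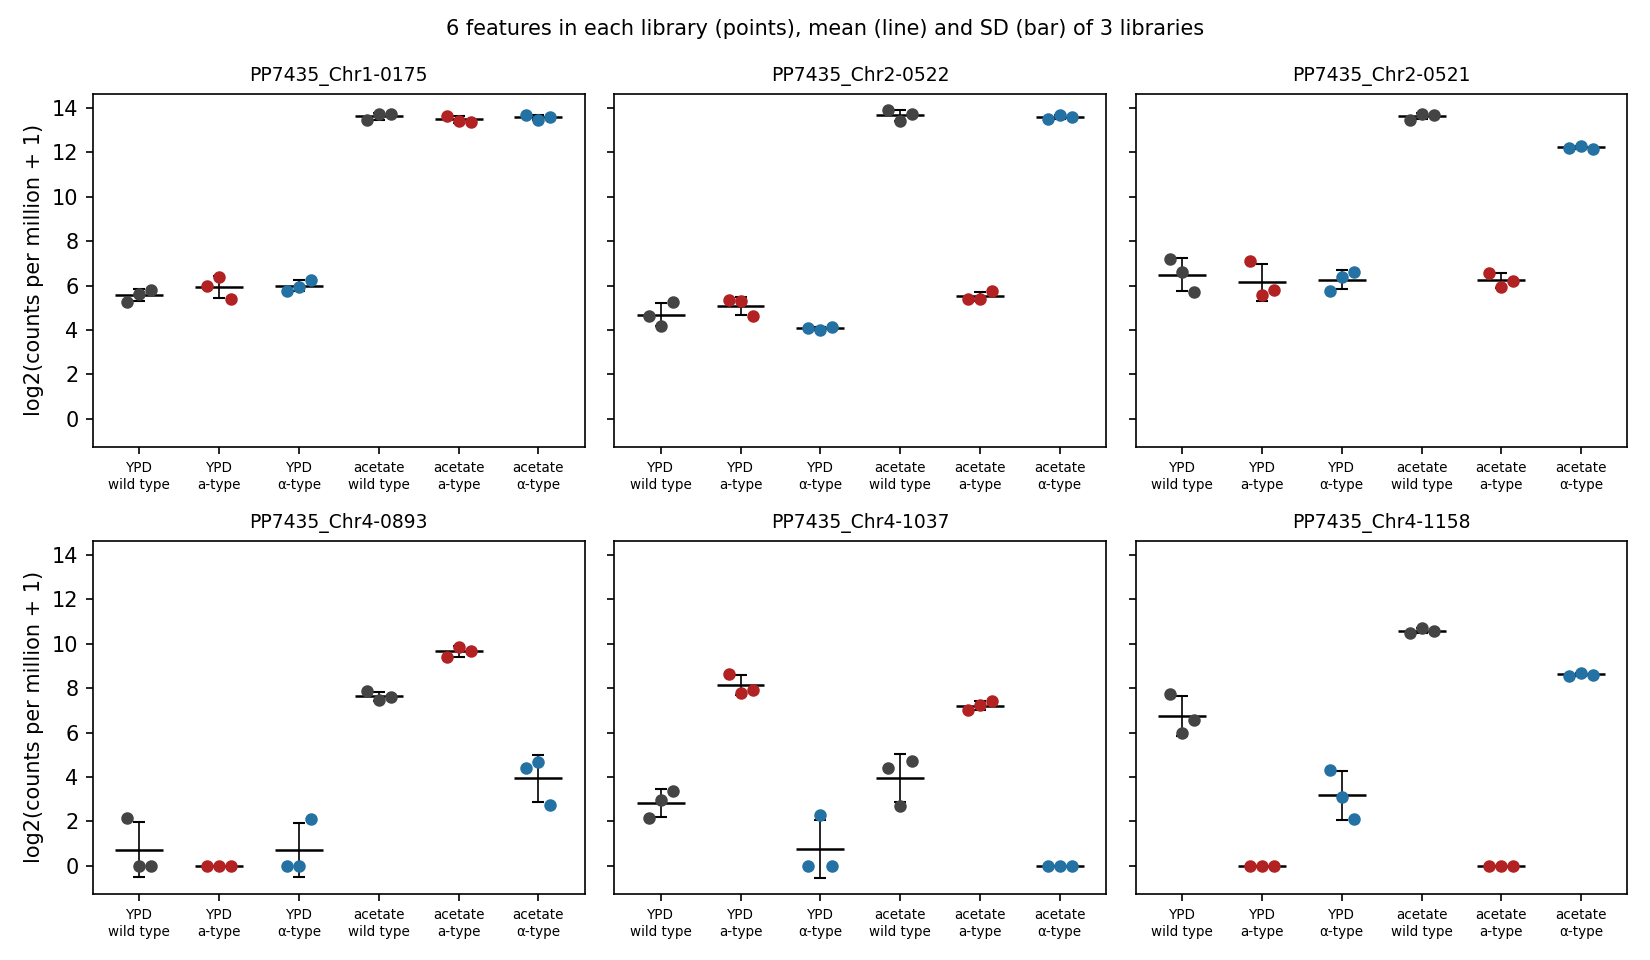
Each panel shows a feature in the 18 libraries, with log2(CPM + 1) on the vertical axis, points for libraries, lines for means and bars for the SD of 3 libraries. PP7435_Chr1-0175 rose in acetate in every strain, PP7435_Chr2-0522 reached 13279 CPM in wild type and 12522 CPM in α-type but 45.0 CPM in a-type, and PP7435_Chr4-1158 had 0 counts in the 6 a-type libraries.

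Wild type was compared with each heterothallic strain. In acetate, 181 features were higher and 435 lower in a-type than in wild type, and 124 were higher and 372 lower in α-type. PP7435_Chr4-1158 was at least 1077-fold lower in a-type, against 1551 ± 123 CPM in wild type. PP7435_Chr2-0208 had 5.62 ± 3.73 CPM in wild type, 60.2 ± 0.529 CPM in a-type (log2 fold change 3.31, SE 0.41, adjusted p = 1.16e-06) and 58.1 ± 7.44 CPM in α-type (log2 fold change 3.25, SE 0.41, adjusted p = 2.1e-06). PP7435_Chr4-0001 and PP7435_Chr4-0074, both with a coding length of 918, had equal counts in all 18 libraries and cannot be told apart. Their summed counts were 139 in acetate wild type, 12 in YPD wild type and 0 in the 12 heterothallic libraries. Whether the sequence of these features or of PP7435_Chr4-1158 differs between the strains was not tested. PP7435_Chr4-0003 and PP7435_Chr4-0072, with coding lengths of 3138 and 3135, are uncertain because kallisto can divide reads between near-identical copies, which these may be: in acetate wild type they had 462 and 0 counts, and in acetate a-type 0 and 1089.

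The features lower in the heterothallic strains overlapped. In acetate, 340 features were lower in both a-type and α-type than in wild type, 109 of them by at least 4-fold in both by the fitted values, and 98 were higher in both. In 20 simulated data sets with unchanged acetate groups and the same shared wild-type libraries, neither count rose above 0, and independent lists would share 33.8 and 4.69. The simulated sets were tested with the joint spread, which is too large for acetate, so counts of 0 were likely in advance. They cannot show how often a shared wild-type error adds a call in the other strain. The covariance of the log2 fold changes was 0.715, against a mean of 0.0547 in the simulations. The 3 wild-type libraries could not be split into parts of at least 2, so part of the excess may come from the shared controls. The 340 features took 27.8% of the counts in acetate wild type, 9.52% in acetate a-type, 11.2% in acetate α-type and 9.17% in YPD wild type. They were selected on the acetate values, in which 275 of them rose from YPD to acetate in wild type, 97 in a-type and 122 in α-type, with median log2 fold changes of 2.26, 0.17 and 0.34.

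**Figure D3:**
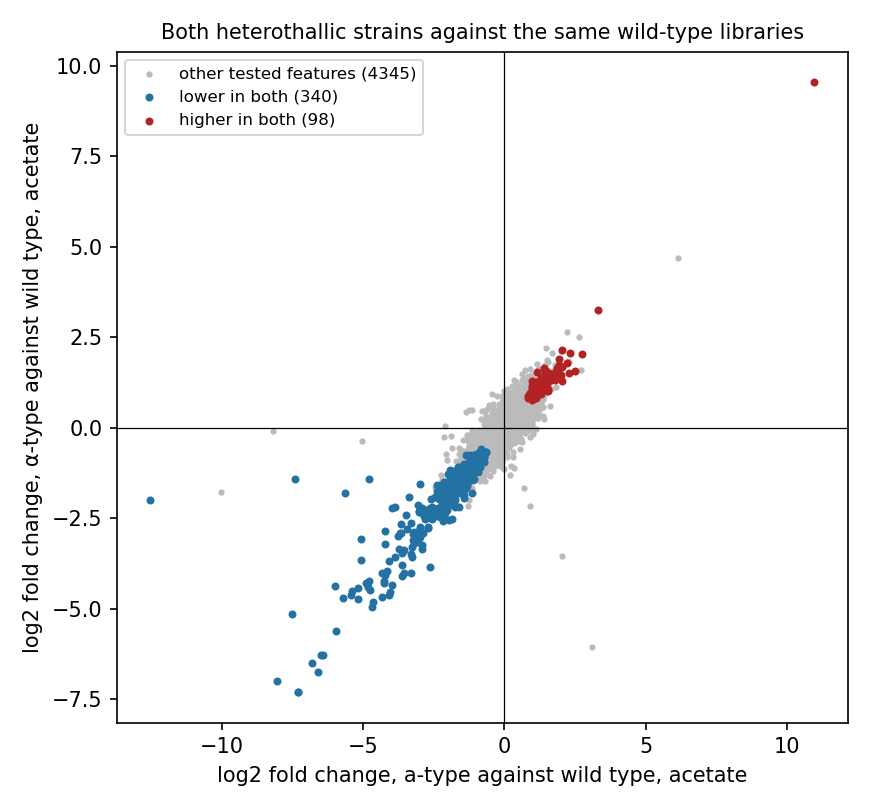
Each point is a tested feature, with the log2 fold change of a-type against wild type in acetate on the horizontal axis and that of α-type against wild type on the vertical axis. The 340 features lower in both and the 98 higher in both are colored, and both axes share the 3 wild-type libraries.

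The balance of calls between the directions depended on scaling and on the libraries fitted. The mean TMM factor was 0.816 for acetate wild type, 1.06 for acetate a-type and 1.04 for acetate α-type. With upper-quartile scaling, 52.7% of the calls between a-type and wild type were higher in a-type, against 29.4% with TMM, and 49.1% between α-type and wild type were higher in α-type, against 25%. That scaling moved the median log2 fold change of all features from 0.06 to 0.27 for a-type and from 0.06 to 0.28 for α-type. Fits of the compared libraries alone gave 1327 and 1314 calls in place of 616 and 496, of which 44.3% and 45.7% were higher in the heterothallic strain. Tests against a log2 fold change of 1, with TMM, gave 180, with 13 higher and 167 lower in a-type, and 143, with 5 higher and 138 lower in α-type. Without wild-type replicate 2 the count of 496 was 320.

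In YPD, 20 features differed between a-type and wild type, 4 higher and 16 lower in a-type. PP7435_Chr4-1158 had 0 counts in a-type against 121 ± 77.7 CPM in wild type, at least 39.8-fold lower, and PP7435_Chr4-1037 was higher in a-type, at 287 ± 95.9 against 6.51 ± 2.92 CPM (log2 fold change 5.46, SE 0.53, adjusted p = 3.67e-06). Between α-type and wild type 2 features passed, both lower in α-type: PP7435_Chr4-1169 at 55.3 ± 17.8 against 732 ± 158 CPM (log2 fold change -3.73, SE 0.34, adjusted p = 3.1e-07) and PP7435_Chr4-1158 at 9.93 ± 8.06 against 121 ± 77.7 CPM (log2 fold change -3.56, SE 0.52, adjusted p = 0.0026). The count of 2 was 1 when the libraries were fitted alone and 6 without α-type replicate 2. The count of 20 was 2 when the libraries were fitted alone, 5 with upper-quartile scaling and 53 with DESeq2. It was 59 without wild-type replicate 2, 51 without a-type replicate 1, 12 without a-type replicate 2 and 3 without wild-type replicate 3.

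The strains were also compared in their response to the medium. Between a-type and α-type 7 features passed the interaction test in the joint fit, where the difference in response, a-type minus α-type, was positive for 2 and negative for 5. With each medium fitted alone with its own spread, 5 of these 7 passed. The response of PP7435_Chr2-0522 was lower in a-type by a log2 difference of -9.21 (SE 0.45, adjusted p = 4.86e-13), and that of PP7435_Chr2-0521, which had 75.2 ± 17.9 CPM in acetate a-type, 4801 ± 246 CPM in acetate α-type and 12768 ± 1176 CPM in acetate wild type, by -6.003 (SE 0.49, adjusted p = 2.13e-08). For PP7435_Chr3-2788 the difference was positive (log2 difference 2.78, SE 0.35, adjusted p = 3.61e-05). Between a-type and wild type 330 features passed, with the difference in response positive for 86 and negative for 244, and between α-type and wild type 199 did, positive for 36 and negative for 163. The sign of such a difference can come from the wild-type response as well as from that of the heterothallic strain. PP7435_Chr4-0221 reached 894 ± 147 CPM in acetate wild type, 9.58 ± 9.14 CPM in a-type and 11.2 ± 3.77 CPM in α-type, with a log2 difference in response of -7.40 between α-type and wild type (SE 0.64, adjusted p = 2.35e-08). With upper-quartile scaling the positive share was 39.6% against 26.1% for a-type and 36.4% against 18.1% for α-type, and tests against a log2 fold change of 1 gave 110 and 64 features. DESeq2 gave 14 in place of 7 features and 305 in place of 199.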

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

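The tests of depth, scaling, a mixed culture, a separate wild-type batch and divided reads, the intervals from the YPD libraries alone and the interaction test with the own spread of each medium were chosen after the results they bear on were seen, and those of scaling, a mixed culture and the own spread replaced earlier versions with other bounds. The responses to the medium differed between strains by an interaction test for 7 features (a-type against α-type), 330 features (a-type against wild type) and 199 features (α-type against wild type). The log2 differences between a-type and α-type were 3.38 for PP7435_Chr3-0313 (which did not pass with the own spread of each medium, 3.40, adjusted p = 0.0558), 2.78 for PP7435_Chr3-2788, -9.21 for PP7435_Chr2-0522 and -6.003 for PP7435_Chr2-0521. Between a-type and wild type they were 9.73 for PP7435_Chr4-0072, 4.08 for PP7435_Chr4-0578, -11.21 for PP7435_Chr1-1164 (-7.50, adjusted p = 1, without YPD a-type replicate 1) and -10.28 for PP7435_Chr4-0003. Between α-type and wild type they were 9.59 for PP7435_Chr4-0072, 3.94 for PP7435_Chr2-0063 (SE 0.94; 2.39, adjusted p = 0.11, without YPD wild-type replicate 3, which had 147.7 CPM against 24.0 and 17.2 in the others), -8.97 for PP7435_Chr1-1164 and -7.40 for PP7435_Chr4-0221. Fitted values for PP7435_Chr1-1164, PP7435_Chr4-0003 and PP7435_Chr4-0072 rest on groups with 0 counts and are no bounds. The 4.08 of PP7435_Chr4-0578 (SE 1.09, adjusted p = 0.0209) rests on few counts, 12 in YPD a-type and 6 in acetate wild type. With PP7435_Chr4-0003 and PP7435_Chr4-0072 summed, the difference in response was 0.10 (adjusted p = 0.932) between a-type and wild type and 0.00439 (adjusted p = 0.997) between α-type and wild type, so the values of 9.73, -10.28 and 9.59 did not hold for the pair.

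The libraries were regrouped between the strains within each medium. Besides the real grouping, only a random draw of the possible groupings was run, so the shares and highest counts are partial. By the share of these groupings that reached the real count, chance could not be excluded for these counts. Of 33 groupings each, the real one included, 4 gave at least 7 features (highest other 7), 2 gave at least 330 (highest other 507) and 3 gave at least 199 (highest other 253). For both comparisons with wild type, every other grouping that reached the real count had kept the real strains in acetate and regrouped only YPD. The groupings that mixed the acetate strains gave at most 1 and 0 features there. Groupings that kept the acetate strains still held the strain difference in acetate, so they cannot test chance for it. Mixed groupings put both strains into the same acetate group, where any strain difference adds to the spread within the group and lowers the count. The 6 acetate libraries of a comparison also allow only 10 groupings into 3 and 3, too few for a share under 0.05. The mixed groupings thus cannot decide whether chance is the source of the acetate part of the 330 and 199 features. For a-type against α-type, 2 of the 3 others that reached 7 kept the acetate strains and 1 did not.

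In acetate, 340 features were lower in both heterothallic strains than in wild type. A wild-type culture that only mixed a-type and α-type cells would lie between them, but wild type lay above both for 255 features under the least favorable of 3 scalings, with the larger of the p-values adjusted over all tested features, which argues against a mixture alone. Upper-quartile scaling kept 76.8% of the 340 calls and ended 79. The median log2 fold changes of the 340 kept at least 85.5% of their size. They went from -1.73 to -1.52 (median SE 0.30) for a-type and from -1.52 to -1.30 (median SE 0.29) for α-type. Those of the 79 kept at least 77.5% (from -1.05 to -0.84 and from -0.99 to -0.77, median SE 0.28). A common shift took these small changes across the threshold (median adjusted p from 0.0147 to 0.0516 and from 0.0212 to 0.0732). The 79 calls thus depended on the scaling. That shift is small against the median changes of the 340, so the choice among the 3 scalings does not account for their size. The 340 were selected under TMM, which made a large loss unlikely in advance. An error common to the 3 scalings was not tested. Growth or preparation of the wild-type acetate libraries apart from the others cannot be told apart from the strain. In YPD, 0.882% of these features differed from wild type in either strain. Of all tested features, 0.418% did in a-type and 0.0418% in α-type, so a low share was likely in advance. It tells nothing about a separate batch. Contact between cells of both mating types, which only the wild-type culture could hold, may contribute, but no test of it was possible here.

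More features differed between a-type and α-type in acetate (19) than in YPD (3). Acetate libraries thinned to the YPD depth and fitted alone gave 54 features, against 2 in YPD fitted alone, which argues against depth as the cause. The larger spread between YPD replicates is not the whole cause: with the own spread of each medium 6 of the 19 passed the interaction test adjusted over all tested features, which were 5 of the 7 that passed it in the joint fit and PP7435_Chr4-0003, whose reads are uncertain. For the other 13 it stays open, since the 95% interval of the difference between media, with the own spread of each medium, included 0 for 4 of them and all were selected on the acetate values, and so does an effect of mating type that depends on the medium. Among the 12 that did not pass in the joint fit, the YPD interval of the joint fit included the acetate change for 2, which met the bound written beforehand against this explanation, and intervals from the 6 YPD libraries alone included it for 4, but that bound was too lenient, because such intervals leave out the error and the selection of the acetate values.

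PP7435_Chr4-0003 and PP7435_Chr4-0072 changed in opposite directions in acetate. Between α-type and wild type their summed counts differed by 0.00157 on the log2 scale (SE 0.23, adjusted p = 0.998), so a division of reads between near-identical copies is a candidate explanation for the higher PP7435_Chr4-0072 there, where PP7435_Chr4-0003 alone did not pass the threshold (adjusted p = 0.0968). Between a-type and wild type the sum was higher in a-type by 0.92 (SE 0.23, adjusted p = 0.00618), and divided reads do not account for this rise of the sum. In YPD the sum was higher in a-type by 0.83 (SE 0.27, adjusted p = 0.227), which did not pass. The division varied among acetate α-type replicates: PP7435_Chr4-0003 and PP7435_Chr4-0072 had 0 and 216 counts in replicate 1. They had 93 and 118 in replicate 2, and 88 and 93 in replicate 3. By contrast, PP7435_Chr4-0003 had 0 counts in every acetate a-type library, and PP7435_Chr4-0072 had 0 in every acetate wild-type library. Whether divided reads account for the opposite directions of the 2 features between a-type and wild type stays open. Sequence differences between the strains in these copies were not tested.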

How the results depend on the processing

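The fits of a single medium, the thinned libraries, the summed pairs and the interaction test with the own spread of each medium were chosen after the data were seen. Counts within 1.5 times the joint edgeR result are not repeated. Tests against a log2 fold change of 1 gave 1151, 685 and 805 features for acetate against YPD in wild type, a-type and α-type, 11 for a-type against α-type in acetate, 3 for a-type against wild type in YPD, 180 and 143 for a-type and α-type against wild type in acetate, and 110 and 64 for their responses. This test asks for a larger change. Fits of the compared libraries alone gave 55 for a-type against α-type in acetate, 2 and 1 for a-type and α-type against wild type in YPD, and 1327 and 1314 in acetate, and fits of the 9 libraries of a medium gave 55, 2, 1, 1391 and 1257. In such fits acetate has its own smaller spread and YPD its own larger one. Alone, 44.3% and 45.7% of the acetate calls against wild type were higher in the heterothallic strain. Thinned acetate libraries gave 54, 1025 and 972. DESeq2 gave 53 for a-type against wild type in YPD, 14 for the response of a-type against α-type and 305 for that of α-type against wild type, and upper-quartile scaling gave 5 for a-type against wild type in YPD; the cause was not tested. Upper-quartile scaling also moved the median of all features to -0.15 for acetate against YPD in wild type, and to 0.17 and 0.28 for the responses against wild type.

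Leaving out a library gave 11 to 16 features for a-type against α-type in acetate, 3 to 59 for a-type against wild type in YPD, 2 to 6 for α-type against wild type in YPD (6 without α-type replicate 2) and 320 to 473 for α-type against wild type in acetate (320 without wild-type replicate 2). Of 788 tests of named features under an alternative, the summed pairs left out, 756 kept their direction and side of the threshold, 32 lost the threshold and 0 changed direction. Named features were selected as the largest changes in the same libraries, so most were likely to hold in advance. With mirrored pairs summed, 3 of 9 tests of their named features kept both, 3 lost the threshold and 3 changed direction: PP7435_Chr4-0072 from -7.37 to 1.72 (adjusted p = 6.9e-06) for acetate against YPD in wild type, and PP7435_Chr4-0003 from -10.05 to 0.92 (adjusted p = 0.00618) for a-type against wild type in acetate and from -10.28 to 0.10 (adjusted p = 0.932) for the difference in response.

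Replicate numbers gave no sign of a pairing: correlations of the deviations of same-numbered libraries ran from -0.32 to 0.25, and in 0 of 9 comparisons were all above 0.1. With so few libraries per group, this cannot exclude a pairing of the same cultures across media. The replicate number was also used as a block, set separately for each strain for acetate against YPD and for the responses. The counts were 2153, 1657 and 1785 for acetate against YPD in wild type, a-type and α-type, 3 and 18 for a-type against α-type in YPD and acetate, 18 and 552 for a-type against wild type, 2 and 461 for α-type against wild type, and 7, 227 and 136 for the responses. The YPD depth limits features near 10.3 CPM per library.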

Other observations

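The test on neighbouring features was written before its result was seen, and the groupings of libraries were planned. The features higher in both heterothallic strains than in wild type in acetate, 98 in number and selected on the acetate values, took 1.42% of the counts in acetate wild type, 4.47% in a-type and 4.05% in α-type, against 4.07% in YPD wild type.

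The YPD libraries varied along an axis that crossed the strains. On the main principal component of the 9 YPD libraries, which held 23.7% of their variance, wild-type replicates 1 and 3 lay at -20.0 and -30.0, a-type replicate 1 at -22.0 and α-type replicate 3 at -13.6, while wild-type replicate 2 lay at 19.4, a-type replicates 2 and 3 at 1.48 and 28.6, and α-type replicates 1 and 2 at 14.6 and 21.6. Groupings of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In YPD, 4 of them gave at least the real 3 features for a-type against α-type (highest other 161), 2 gave at least the real 20 for a-type against wild type (highest other 302) and 3 gave at least the real 2 for α-type against wild type (highest other 112), which points to a structure of the YPD samples other than strain. For a-type against α-type, a-type against wild type and α-type against wild type in acetate, and for acetate against YPD in each strain, 1 of the 10 groupings, the real one, gave as many features (19, 616, 496, 2339, 1890 and 2004), and the highest other was 0.

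A hypothesis was that neighbouring features change together. Serial numbers follow the chromosome at least in part, since 62.0% of 2114 consecutive pairs with coding lengths of at least 900 had the same pair of lengths side by side in assembly ASM2700v1 of strain GS115, against 1.39% after shuffling. The 340 features lower in both heterothallic strains in acetate held 39 pairs with consecutive serial numbers, against a mean of 18.9 in 10000 random sets of the same size (permutation p = 0.0002). This is consistent with neighbours changing together, but random sets also fell short for the 664 features that rose in acetate in all 3 strains (111 pairs against a mean of 72.2), so the clustering is not particular to the comparison with wild type.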
